A study of Homo sapiens with 8 samples.

How the data were processed

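RNA levels were measured in MCF7 and T47D, a pair of estrogen-dependent human breast cancer cell lines, after transfection with either a negative control siRNA or an siRNA against RHBDD2. Per the labels, each line and siRNA was profiled in duplicate, which gives 4 groups of 2 arrays and 8 arrays in all. Per the labels' protocols, MCF7 was grown in RPMI and T47D in DMEM before lipid transfection, so medium and line cannot be told apart. Total RNA was amplified with aminoallyl UTP and labelled with Cy5, and each sample was hybridised alone to 1 oligonucleotide array, per the labels. The labels name duplicate experiments and do not say that these were separate cultures, so the p-values measure only the spread between the duplicate arrays, which may be technical.

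The deposited scanner files give, per the file headers, a raw intensity, a background-subtracted intensity and a globally normalized intensity for each spot. In the values, the background-subtracted intensity was the raw intensity minus 1 constant per array, and the normalized intensity was that value divided by 1 factor per array, which set the median probe of every array at 25. The authors left a spot blank in both columns where it lay close to the background. The deposited series table held the same normalized intensity with 1 decimal and no control spots. The image analysis software is not given in the sources used here.

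Raw intensities were corrected with the normexp model over all spots of an array, control spots included, with an offset of 50. Control and blank spots, 2996 of the 27456 spots of an array, were then left out, and probes that the files mark NG were set to missing on that array. The 8 arrays were quantile-normalized on the log2 scale. Fold changes are therefore on the log2(corrected intensity + 50) scale, which understates the change of dim probes. Intensities printed for single genes are the deposited normalized intensities, as mean ± SD of 2 arrays. Of 24460 probes, the 23374 with a deposited value on both arrays of at least 1 group were tested.

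The design fixed in advance allowed a deposited column to be used as it was if it was already corrected and normalized. The whole-number normalized column was tried first in this role. Its rounding gave many duplicate pairs with no spread at all, and after its counts had been seen it was replaced by the raw intensities processed as above. The whole-number column is reported as an alternative.

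A linear model with 1 mean per group was fitted to each probe in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with empirical Bayes moderation, 4 residual and 2.74 prior degrees of freedom. The contrasts were RHBDD2 siRNA minus control siRNA in MCF7 and in T47D, the mean of these 2 differences, the T47D difference minus the MCF7 difference, and T47D minus MCF7 under control siRNA. Tests were two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. Every adjusted p printed for a gene comes from this limma model. With 2 arrays per group, the number of arrays limits the precision.

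Gene lists of pathways, complexes and cell type markers, 37 in number with 956 of 1001 genes measured, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. A gene with several probes was represented by its brightest probe. Camera with a correlation estimated from the arrays, and fry, a rotation test of whether the genes of a list move on balance one way, were alternatives. With an estimated correlation camera also has fewer degrees of freedom, the 4 residual ones. A call lost there can therefore come from either change. In every list past the threshold, the median, the mean and the test had the same sign. The lists, the groups, the models, the probe filter, the rule for named genes and all alternatives not said to be added later were chosen before the data were examined.

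The rule for named genes was as follows. RHBDD2 was reported in every array. In each line, the 12 genes with the largest rise and the 12 with the largest fall were named among those past the threshold whose siRNA arrays both lay beyond both control arrays and which were measured on both arrays of the brighter group. All were taken if fewer passed, and if fewer than 5 passed in a line, the 10 genes with the smallest p were given as values and not as calls. For the mean of both lines, up to 10 per direction were allowed, if past the threshold and of the same direction in both lines. For the difference in response, up to 6 with the smallest adjusted p were named, for the lines under control siRNA the 8 highest in each, and for each list described up to 4 members with the smallest p. Probes with several genes and loci without an approved symbol were skipped, and any gene could be left out of the text but none replaced.

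Gene names came from the scanner files. Of these names, 17606 were current symbols in a table of RefSeq genes of assembly GRCh38.p14, 2933 were updated through a synonym and 2045 were kept as in the files, while 1876 probes had no name. The files name no genome build, and no coordinates are given. Where a probe was blank on both arrays of a group, its fold is a bound: the mean of the brighter group against, per array, the higher of the lowest signal among probes with a value and the dim probe's own.

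The model was tested on simulated data with the control means of the real arrays and a spread drawn from the fitted prior. The noise was independent between probes. For the MCF7 comparison over 23374 probes, 84 of 100 probes changed by 0.5 on the log2 scale and 98 of 100 changed by 1 were called, with 6 of 188 calls among unchanged probes. No probe was called in T47D, where nothing had been changed. A list of 31 genes shifted by 0.15 on the log2 scale was called, and 0 of 20 unshifted lists were. Because the simulated genes did not vary together, this does not show how often camera calls a list wrongly in the real arrays.

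The alternatives were the raw column plus 50 without normexp, median scaling of each array, no probe filter, a filter to probes with a value on all 8 arrays, the deposited series table, an intensity trend with robust moderation, only the arrays of 1 line, an additive model, the replicate number as a block, each array left out in turn, and, for lists, fry, an estimated correlation and the mean of all probes of a gene. Median scaling acted on log2 values with the offset of 50 already added. The offset weighs more on a dimmer array, so this setting leaves differences that depend on array brightness. Chosen after seeing the data were the deposited whole-number values, these values plus 16, and cyclic loess normalization. Figures were drawn with python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.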

Results

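The data are 8 one-colour oligonucleotide arrays of the breast cancer lines MCF7 and T47D, with 2 arrays for each line under control siRNA and 2 under RHBDD2 siRNA. RHBDD2 encodes a rhomboid-domain membrane protein, and the design asks which transcripts differ once it has been silenced. The median raw intensity per array ran from 32 to 42 in MCF7 and from 53 to 71 in T47D, over a background of 7.08 to 9.76 in MCF7 and 12.0 to 13.8 in T47D. Between 91.74% and 95.29% of probes had a deposited value on an array. Across probes, duplicate arrays correlated with r of 0.9974 to 0.9989, arrays of the other siRNA in the same line with 0.996 to 0.9979, and arrays of the other line with 0.9364 to 0.9388. Probes are not independent, and these r describe the arrays only.

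RHBDD2 was lower in the MCF7 arrays labelled RHBDD2 siRNA, and no difference was detected in the T47D arrays with that label. In MCF7 its deposited intensity was 374.5 ± 7.78 under control siRNA (380 and 369) and 209 ± 14.1 under RHBDD2 siRNA (199 and 219), which left 55.8% of the control level. In T47D the intensities were 356.5 ± 43.1 under control siRNA (387 and 326) and 346 ± 18.4 in the arrays labelled RHBDD2 siRNA (359 and 333), or 97.1% of control. On the log2 scale RHBDD2 fell by 0.69 in MCF7 (95% interval -0.89 to -0.49, limma adjusted p = 0.023), and it ranked 22 in size among the falls called in that line. The T47D value was -0.08 (95% interval -0.28 to 0.12, adjusted p = 0.732). The difference between the lines was 0.62 ± 0.118 (SE, 95% interval 0.335 to 0.898). Adjusted over all probes, it did not pass the threshold (limma adjusted p = 0.0657). Because the T47D arrays do not show the silencing their label names, every T47D difference below is one between arrays labelled RHBDD2 siRNA and control arrays. The MCF7 call was lost when any MCF7 array was left out, which leaves a group of 1 array and less power. The log2 change was then -0.676 and -0.71 without control arrays 1 and 2, and -0.605 and -0.786 without RHBDD2 siRNA arrays 1 and 2. The call was also lost on the deposited series table (adjusted p = 0.068, log2 change -0.84) and with the replicate number as a block (adjusted p = 0.0639). Without T47D control arrays 1 and 2 the T47D value was 0.03 and -0.18.

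**Figure D1:**
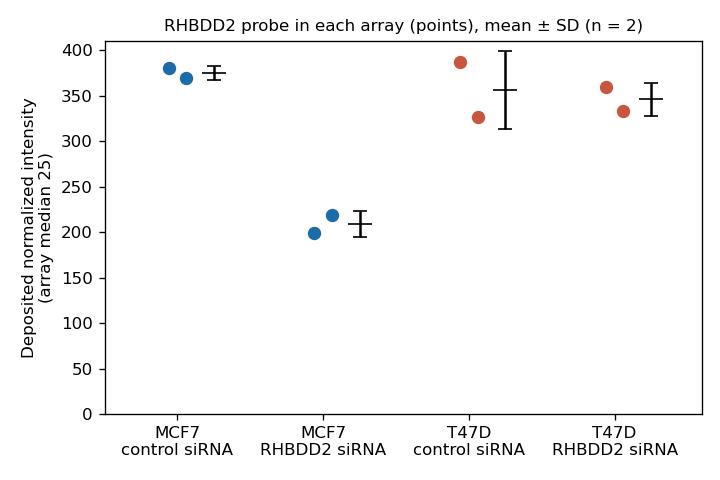
Deposited normalized intensity of the RHBDD2 probe (y axis, scaled so that the median probe of an array is 25) in each of the 8 arrays (points), with mean and SD of 2 arrays per group (bars). The MCF7 RHBDD2 siRNA arrays, at 199 and 219, lie below the MCF7 control arrays at 380 and 369, while the 4 T47D arrays lie between 326 and 387.

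In MCF7, 7 gene lists were lower under RHBDD2 siRNA: oxidative stress, glycolysis and hypoxia, immediate early genes, mitosis, ribosome biogenesis, protein folding in the endoplasmic reticulum and oxidative phosphorylation. With an estimated correlation none of the 7 was past the threshold (lowest adjusted p = 0.0692 with an estimated correlation). The strongest single fall was that of ATP6V0C, a subunit of the proton pump of lysosomes, from 655 ± 250 to 100 ± 35.4 (SD, n = 2 arrays). KCNH2, a potassium channel, fell from 95.5 ± 7.78 to 29.5 ± 2.12, and the interferon-induced exonuclease ISG20 fell from 777.5 ± 51.6 to 366 ± 42.4. Among rises, the zinc finger gene ZNF652 went from 46.5 ± 0.707 to 121.5 ± 16.3 and the homeobox gene PBX2 from 166 ± 8.49 to 317 ± 14.1. In all, limma called 108 probes higher and 193 lower of 23374, which covered 291 named genes.

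Further rises in MCF7 were those of CCDC71 (log2 change 0.73), the scavenger receptor COLEC12 (0.71), the small GTPase ARL2 (0.66), the selenium-binding protein SELENBP1 (0.59), the homeobox gene MEIS3 (0.50), the kinase ULK3 (0.44), the tumour suppressor ING1 (0.42), the pseudogene SLC26A10P (0.42), the nuclear pore gene NUP93 (0.41) and ZNF467 (0.41). Further falls were those of the adenylate cyclase ADCY3 (-0.85), ACO1, the iron-regulated cytosolic aconitase (-0.85), MAT2A, which makes S-adenosylmethionine (-0.84), the disulfide isomerase PDIA3 (-0.84), the cyclin-dependent kinase phosphatase CDKN3 (-0.84), the ribosome assembly gene BYSL (-0.83), the molybdenum cofactor gene MOCS2 (-0.80), malic enzyme ME1 (-0.80) and the kinase LIMK2 (-0.80). With ATP6V0C (-2.28), KCNH2 (-1.01), ISG20 (-0.92), ZNF652 (1.02) and PBX2 (0.86), these 24 genes had limma adjusted p between 0.0105 and 0.0418 and SE between 0.0317 and 0.255. A second probe of SLC26A10P, ACO1 and BYSL moved the same way without passing the threshold, and of the other 2 LIMK2 probes 1 did.

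**Figure D2:**
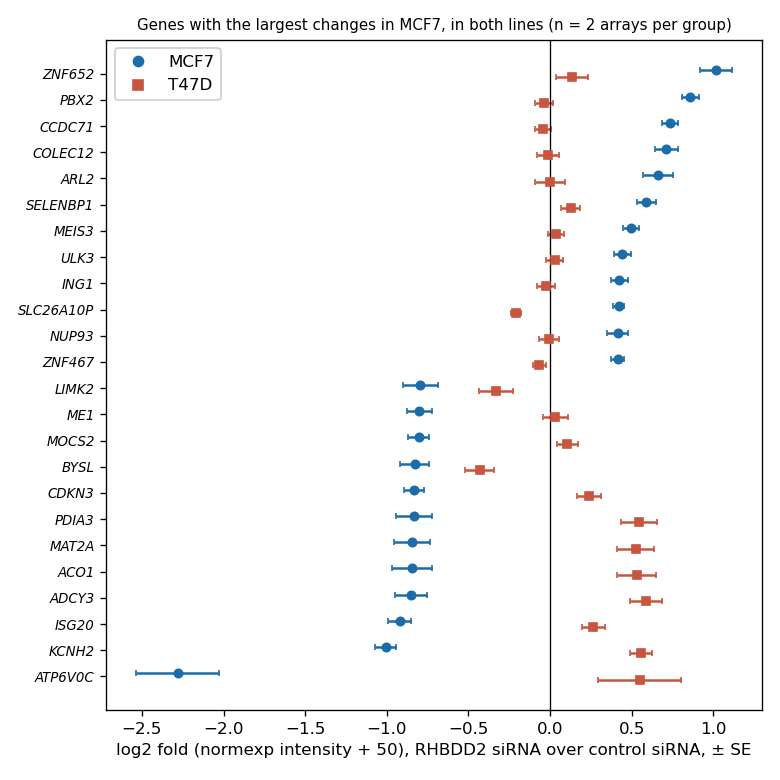
Log2 fold of normexp-corrected intensity + 50 (x axis), RHBDD2 siRNA over control siRNA, for the 12 genes with the largest rises and the 12 with the largest falls in MCF7 (y axis), with SE, in MCF7 (circles) and T47D (squares). MCF7 values run from -2.28 for ATP6V0C to 1.02 for ZNF652. Among the genes that fell in MCF7 the T47D values of BYSL (-0.43) and LIMK2 (-0.33) lie below 0. ME1 among the falls and COLEC12 among the rises are near the floor in T47D.

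The list of oxidative stress genes and NRF2 targets was lower in MCF7 (camera adjusted p = 5.71e-09, and adjusted p = 0.0692 with an estimated correlation). Of its 31 measured members, 6 fell, none rose and 25 did not pass the threshold, while 13 were lower when adjusted over the list alone. The heme-degrading enzyme HMOX1 fell from 168 ± 8.49 to 104 ± 2.83, catalase (CAT) from 161 ± 8.49 to 94 ± 1.41, ME1 from 517.5 ± 31.8 to 267 ± 45.3 and OSGIN1 from 163.5 ± 0.707 to 121 ± 4.24. Genes of glycolysis and hypoxia were also lower as a list (adjusted p = 6.64e-06, and adjusted p = 0.0778 with an estimated correlation). Of 34 measured, 1 fell, the aldolase gene ALDOC (464 ± 9.9 to 248.5 ± 14.8), and 33 did not pass, with 5 lower when adjusted over the list alone. BNIP3L (-0.50), EGLN3 (-0.25) and ENO2 (-0.23) were among those that did not pass.

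Of 28 immediate early genes, which respond first to growth factors, 3 fell and 25 did not pass, with 5 lower when adjusted over the list alone (list adjusted p = 2.95e-04, and adjusted p = 0.11 with an estimated correlation). Those that fell were EGR3 (-0.25), the phosphatase DUSP5 (-0.36) and FOS (-0.18), and EGR1 had a value of -0.42. Of 33 genes of mitosis and G2/M, 3 fell and 30 did not pass, with 4 lower when adjusted over the list alone (list adjusted p = 0.00376, and adjusted p = 0.226 with an estimated correlation). They were the centromere histone CENPA, from 1164 ± 62.2 to 669 ± 1.41, cyclin A2 (CCNA2), from 726 ± 14.1 to 455.5 ± 48.8, and HMMR, from 260.5 ± 13.4 to 166.5 ± 7.78, while MAD2L1 had a value of -0.25. Of 32 genes of ribosome biogenesis and MYC targets, the ribosome assembly genes PES1 (-0.47) and BYSL (-0.83) made up the 2 that fell, and ODC1 (-0.30) and WDR43 (-0.23) were among the 30 that did not pass. That list had 5 lower genes when adjusted over the list alone (adjusted p = 0.00376, and adjusted p = 0.152 with an estimated correlation).

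Of 21 chaperones and folding enzymes of the endoplasmic reticulum, 1 fell and 20 did not pass, with 3 lower when adjusted over the list alone (list adjusted p = 0.0255, and adjusted p = 0.226 with an estimated correlation). PDIA3 fell from 992.5 ± 44.5 to 514.5 ± 44.5, while PPIB (-0.18), ERO1A (-1.02) and SDF2L1 (-0.14) did not pass. Of 50 genes of oxidative phosphorylation, 4 fell and 46 did not pass, with 9 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0255, and adjusted p = 0.31 with an estimated correlation). The 4 were the ATP synthase genes ATP5MC3 (-0.38) and ATP5F1A (-0.74), COX4I1 of complex IV (-0.47) and NDUFB8 of complex I (-0.46). The endoplasmic reticulum list lost its call without MCF7 control array 2 (adjusted p = 0.0713), without RHBDD2 siRNA array 2 (adjusted p = 0.0831) and on the deposited series table (adjusted p = 0.0709). The oxidative phosphorylation list lost its call without control array 2 (adjusted p = 0.0866), without RHBDD2 siRNA array 1 (adjusted p = 0.277) and with fry (adjusted p = 0.0746).

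Lists not past the threshold in MCF7 also held called genes. Among 28 p53 targets the kinase PLK3 (-0.68) and the cell cycle inhibitor CDKN1A (-0.63) fell and 26 did not pass (list adjusted p = 0.167), with 5 lower when adjusted over the list alone. Among 42 interferon-stimulated genes ISG20, IRF1 (-0.34) and BST2 (-0.31) fell and 39 did not pass (list adjusted p = 0.379), with 4 lower and 1 higher when adjusted over the list alone. Among 33 estrogen-responsive genes cyclin D1 (CCND1, -0.43) and FOS fell and 31 did not pass (list adjusted p = 0.1), with 8 lower and 3 higher when adjusted over the list alone. Of 26 genes of cholesterol biosynthesis and uptake, DHCR24 (0.28) and SQLE (0.32) rose, TM7SF2 (-0.28) fell and 23 did not pass (list adjusted p = 0.0847), with 2 higher and 5 lower when adjusted over the list alone. RHBDD2 alone fell among 13 measured members of the rhomboid family (list adjusted p = 0.491), where 2 were higher and 1 lower when adjusted over the list alone. Markers of other cell types were not past the threshold by camera in MCF7: the adjusted p was 0.68 for fibroblasts, 0.68 for immune cells, 0.71 for endothelium and 0.254 for erythroid cells and liver. Fry's mixed test, of change in either direction, put 32 of the 37 lists past the threshold in MCF7. These marker lists were among them (fry mixed adjusted p = 0.000567, 0.0036, 0.000567 and 0.00447), so that test does not set the lists apart.

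Leaving out any MCF7 array leaves a group of 1 array and less power. The MCF7 count fell to few probes or none in each such fit, and nearly all of the named genes lost their call. The loss of power cannot be told apart from calls that hang on 1 array. Leaving out T47D arrays, which enter through the shared spread and the joint normalization, gave 143 and 146 without control arrays 1 and 2, and 607 and 594 without the arrays labelled RHBDD2 siRNA 1 and 2. Median scaling gave 4 probes higher and 138 lower and cyclic loess 27 and 90, while 3 were higher and 19 lower on the deposited series table. Of the 12 named rises, only ZNF652, PBX2, CCDC71 and COLEC12 stayed past the threshold under median scaling, while the 12 named falls all did. With the deposited series table, 3 of the 12 rises and 2 of the 12 falls stayed past it. With the replicate number as a block 7 of the 12 rises and 7 of the 12 falls did, and with a block within line 1 and 5.

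**Figure D3:**
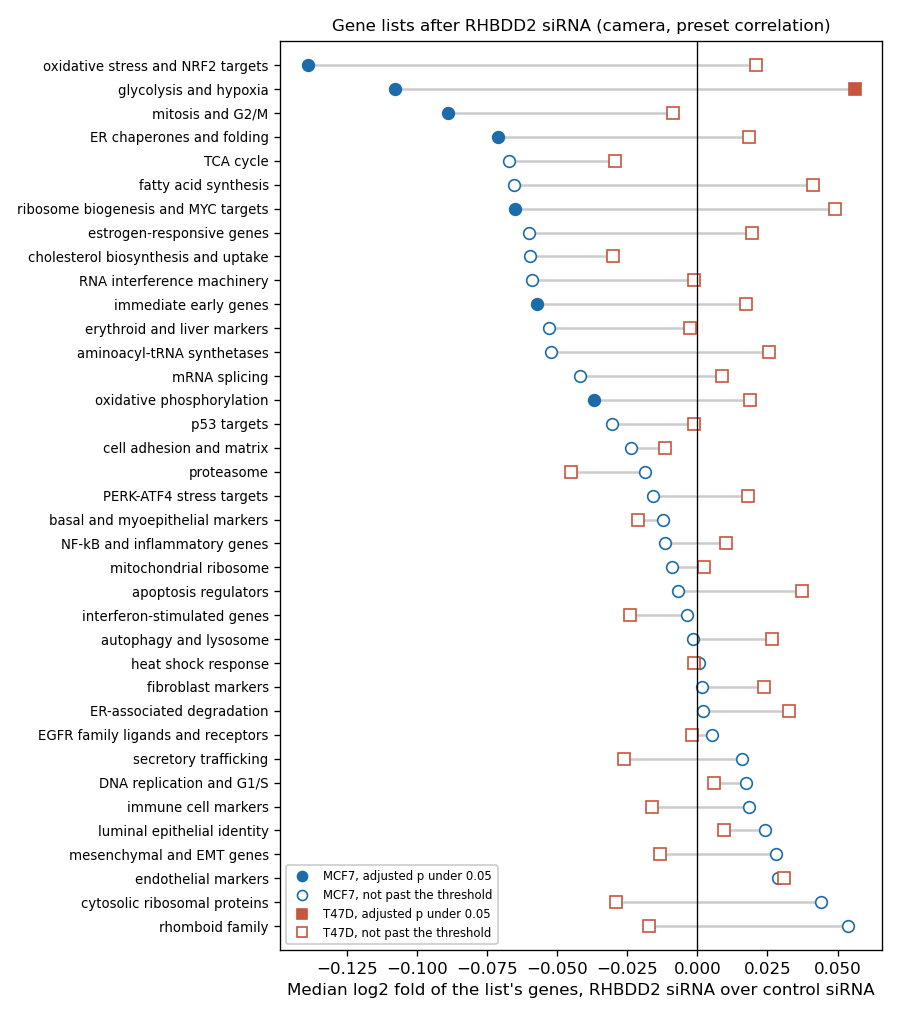
Median log2 fold of the measured genes of each of the 37 lists (x axis), RHBDD2 siRNA over control siRNA, in MCF7 (circles) and T47D (squares), with filled symbols for lists past the adjusted p threshold of 0.05 by camera at a preset correlation. The 7 filled MCF7 symbols lie below 0 and the 1 filled T47D symbol, glycolysis and hypoxia, lies above 0, and with an estimated correlation none is past the threshold.

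In T47D no gene passed the threshold between arrays labelled RHBDD2 siRNA and control arrays. The limma count was 0 of 23374 probes, with a lowest adjusted p of 0.137 and 3538 probes at an unadjusted p under 0.05, and with an intensity trend and robust moderation it was 55. Among the genes with the smallest p, the steroid-responsive co-chaperone FKBP5 was at 520.5 ± 14.8 in control arrays and 691 ± 2.83 in arrays labelled RHBDD2 siRNA (SD, n = 2 arrays), and OLFML3 at 975 ± 39.6 and 1316 ± 15.6. In the same order, the tubulin TUBB4B was at 4332 ± 288 and 5352 ± 365, the lipid transporter ABCA3 at 184 ± 1.41 and 293.5 ± 21.9, and KCNH2 at 58 ± 4.24 and 100.5 ± 6.36. The others were HSD11B2 (0.34), which inactivates cortisol, RTF1 (0.39, its other probe with the opposite sign), CCDC43 (0.24), the olfactory receptor OR2F1 (-0.33) and the cytochrome CYP2B6 (-0.32). Without the T47D array labelled RHBDD2 siRNA 1 the count was 347, of which 287 were higher, and without array 2 it was 2.

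Genes of glycolysis and hypoxia were higher as a list in T47D arrays labelled RHBDD2 siRNA (camera adjusted p = 0.028, and adjusted p = 0.588 with an estimated correlation). None of its 34 measured genes passed the threshold, over all probes or adjusted over the list alone, and 27 of 34 values were above 0. PDK1, which inhibits pyruvate dehydrogenase, had a value of 0.15, the glycolytic enzymes GPI and ENO2 had 0.26 and 0.19, and the MYC antagonist MXI1 had 0.28. The list lost its call without T47D control array 1 (adjusted p = 0.238) and without the array labelled RHBDD2 siRNA 1 (adjusted p = 0.316). It was not past the threshold under median scaling (adjusted p = 0.553), cyclic loess (adjusted p = 0.0677) or the mean of all probes of a gene (adjusted p = 0.1). Without the array labelled RHBDD2 siRNA 2, 4 lists were past the threshold. With all arrays the other 36 lists were not, with adjusted p of 0.446 for fibroblast, 0.823 for immune, 0.566 for endothelial and 0.856 for erythroid and liver markers.

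For the mean of both lines, no gene passed the threshold and 1 list did. Limma gave 0 of 23374 probes with a lowest adjusted p of 0.107 and 3563 probes at an unadjusted p under 0.05, and 55 with an intensity trend and robust moderation. RHBDD2 had a mean value of -0.38 (adjusted p = 0.107). Oxidative stress genes and NRF2 targets were lower as a list (camera adjusted p = 0.00323, and adjusted p = 0.409 with an estimated correlation), with none of 31 past the threshold over all probes and 9 lower when adjusted over the list alone. In T47D by itself 21 of the 31 values were above 0 and 10 below, with a median of 0.021, so the lower mean came from MCF7. CAT (-0.22), OSGIN1 (-0.15) and HMOX1 (-0.16) were among the genes with the smallest p, and each fell in MCF7 and had a T47D value above 0 that did not pass. ME1 (-0.39) was near the floor in T47D, at 2 ± 0 and 3.5 ± 0.707, so its mean value came from MCF7. Without the T47D array labelled RHBDD2 siRNA 1 the count of probes was 364, and without array 2 it was 2. The list was not past the threshold on the deposited series table (adjusted p = 0.338), and 2 lists were past it without MCF7 control array 1 and 3 without T47D control array 1.

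The response differed between the lines for 261 probes, of which 196 had a higher and 65 a lower value in T47D than in MCF7. KCNH2 differed by 1.56 ± 0.0934 on the log2 scale (SE, T47D minus MCF7), with -1.01 in MCF7 and 0.56 in T47D. The tRNA export receptor XPOT differed by 1.09, the mitochondrial fatty acid enzyme ACADVL by 0.94, HMOX1 by 0.74 and the growth kinase MTOR by 0.55, each with a value below 0 in MCF7 and above 0 in T47D. SLC26A10P differed by -0.63, with 0.42 in MCF7 and -0.21 in T47D. The SE of these 6 genes lay between 0.0444 and 0.0934, and their limma adjusted p was 0.0183. Of the 196 probes, 194 had an MCF7 value below 0 and a T47D value above 0, and of the 65, 60 had the reverse, a tally that the selection for a large difference itself favours. Across all probes the responses of the lines correlated weakly and negatively (Pearson r = -0.119, Spearman rho = -0.0491), and probes are not independent replicates.

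By list, 10 of 37 lists had a higher value in T47D than in MCF7, with camera adjusted p from 5.16e-09 to 0.0418, and none was past the threshold with an estimated correlation. For oxidative stress genes and NRF2 targets (adjusted p = 0.0507 with an estimated correlation) 4 of 31 genes differed and 27 did not pass, with 8 higher when adjusted over the list alone. The 4 were HMOX1 (0.74), CAT (0.72), OSGIN1 (0.33) and ME1 (0.83). ME1 could not show a fall in T47D, where it was near the floor at 2 ± 0 under control siRNA and 3.5 ± 0.707 in arrays labelled RHBDD2 siRNA, so its difference restates the MCF7 fall. For glycolysis and hypoxia (adjusted p = 0.0507 with an estimated correlation) ALDOC (0.93) differed and 33 of 34 did not pass, with 7 higher when adjusted over the list alone. For immediate early genes (adjusted p = 0.0921 with an estimated correlation) EGR3 (0.46) differed and 27 of 28 did not pass, FOS (0.24) among them, with 5 higher when adjusted over the list alone. For ribosome biogenesis and MYC targets (adjusted p = 0.105 with an estimated correlation) PES1 (0.58), the polyamine enzyme ODC1 (0.72) and RRS1 (0.36) differed and 29 of 32 did not pass, with 7 higher and 1 lower when adjusted over the list alone.

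For mitosis and G2/M (adjusted p = 0.261 with an estimated correlation) CCNA2 (0.78) and CENPA (0.73) differed and 31 of 33 did not pass, with 7 higher and 1 lower when adjusted over the list alone. For oxidative phosphorylation (adjusted p = 0.261 with an estimated correlation) ATP5F1A (1.15), NDUFB8 (0.64), COX4I1 (0.56) and ATP5MC3 (0.42) differed and 46 of 50 did not pass, with 8 higher when adjusted over the list alone. For chaperones and folding in the endoplasmic reticulum (adjusted p = 0.231 with an estimated correlation) PDIA3 (1.38) differed and 20 of 21 did not pass, with 1 higher when adjusted over the list alone. For fatty acid synthesis (adjusted p = 0.231 with an estimated correlation) the sole call was ME1, which was near the floor in T47D and so restates its MCF7 fall. The other 19 of 20 did not pass, the desaturases FADS1 (0.56) and SCD (0.37) among them, with 6 higher and 1 lower when adjusted over the list alone. For mRNA splicing (adjusted p = 0.261 with an estimated correlation) U2AF2 (0.73) differed and 44 of 45 did not pass, SRSF1 (0.56) among them, with 6 higher when adjusted over the list alone. For estrogen-responsive genes (adjusted p = 0.231 with an estimated correlation) ABCA3 (0.81), the lysosomal protease CTSD (0.96) and CCND1 (0.47) differed and 30 of 33 did not pass, with 8 higher and 1 lower when adjusted over the list alone.

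The count of 261 was 0 without any of the MCF7 arrays or of the T47D control arrays, and 462 and 102 without the T47D arrays labelled RHBDD2 siRNA 1 and 2. It was 0 on the deposited series table and with the replicate number as a block, 22 higher and 1 lower under median scaling, and 116 and 10 under cyclic loess. The estrogen-responsive list lost its call without MCF7 control array 2 (adjusted p = 0.081), MCF7 RHBDD2 siRNA array 1 (0.0949), T47D control arrays 1 and 2 (0.0762 and 0.0792) or the T47D array labelled RHBDD2 siRNA 1 (0.0727), and under cyclic loess (0.108), on the deposited series table (0.115) and with the mean of probes (0.0546). Mitosis genes lost it without MCF7 RHBDD2 siRNA array 1 (adjusted p = 0.103) or T47D control array 1 (0.0719), and oxidative phosphorylation without MCF7 RHBDD2 siRNA array 1 (0.15) and with fry (0.0548). The splicing list lost it without T47D control array 1 (adjusted p = 0.121) or the T47D array labelled RHBDD2 siRNA 1 (0.128), and with fry (0.0909). The endoplasmic reticulum list lost it without T47D control array 2 (adjusted p = 0.0523) or the array labelled RHBDD2 siRNA 1 (0.0743), and fatty acid synthesis without T47D control array 2 (0.0711) or the array labelled RHBDD2 siRNA 2 (0.0709).

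Under control siRNA the lines, which were grown in different media, differed at 10782 probes, with 5447 higher in T47D and 5335 higher in MCF7. The stress-induced regulator NUPR1 was at 2636 ± 128 in T47D and 10 ± 0 in MCF7, and the tight junction gene CLDN1 at 2065 ± 62.2 and 6.5 ± 0.707, its other probe having the same sign without passing. In the same order, the iron exporter SLC40A1 was at 1398 ± 2.12 and 2.5 ± 0.707, and GNG11 at 1540 ± 158 and 6.5 ± 0.707 (SD, n = 2 arrays). The secreted protein PIP was blank on both MCF7 control arrays, at 1809 ± 204 in T47D, and at least 66.0-fold higher in T47D (adjusted p = 3.26e-08). SERPINA6, which carries cortisol in blood, was higher in T47D by 5.43 on the log2 scale, AGR3 by 5.41 and CRIP1 by 5.34. The trefoil peptide TFF1, an estrogen-induced gene, was at 26150 ± 391 in MCF7 and 65.5 ± 0.707 in T47D, the protease PRSS23 at 2331 ± 143 and 20.5 ± 0.707, and the oxidase subunit CYBA at 2006 ± 166 and 19.5 ± 2.12. SULF2, at 1966 ± 65.1 and 21 ± 1.41, SYTL2, at 934 ± 25.5 and 3 ± 0, and SLC7A2, at 904.5 ± 24.7 and 5 ± 1.41, were also higher in MCF7. So were BASP1, at 1758 ± 87.0 in MCF7 and with a value on 1 of 2 T47D control arrays, and LXN, at 824 ± 42.4 and 1 ± 0. Both were near the floor in T47D, and their log2 values (T47D minus MCF7) ran from -11.1 to -5.58 and from -9.92 to -4.55 over the alternatives. Near the floor the size of a fold depends on the offset, so these genes are given without an order. The limma adjusted p of these 16 genes ran from 3.1e-09 to 5.81e-07. Under median scaling, which moved the median of all probes to -0.10 (T47D minus MCF7), the split was 5522 and 8989.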

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

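The tests of an exchange of labels, an array of the other line, the probe's level, silencing, array brightness, dim probes and shared differences between cultures were chosen only after the results were seen, and cyclic loess normalization was added after the data were seen.

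The responses of MCF7 and T47D differed by a test of the difference itself for 261 probes. The named ones, as log2 values of T47D minus MCF7, were KCNH2 (1.564), SLC26A10P (-0.6279), XPOT (1.091), HMOX1 (0.7392), MTOR (0.5484) and ACADVL (0.9415). By the same test 10 lists had a higher response in T47D, with these medians of the difference over their genes: glycolysis and hypoxia 0.166, oxidative stress and NRF2 targets 0.15, immediate early genes 0.131, mitosis and G2/M 0.128, ribosome biogenesis and MYC targets 0.0916, fatty acid synthesis 0.0882, endoplasmic reticulum chaperones 0.0765, estrogen-responsive genes 0.0713, mRNA splicing 0.0492 and oxidative phosphorylation 0.0413. None of these lists was past the threshold with an estimated correlation (lowest adjusted p = 0.0507). Without any of the MCF7 arrays or of the T47D control arrays, 0 probes differed, and without the T47D arrays labelled RHBDD2 siRNA 1 and 2 there were 462 and 102.

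RHBDD2 was lower in MCF7 and no fall was detected in T47D. An exchange of control and RHBDD2 siRNA labels among the T47D arrays is argued against, since the largest RHBDD2 difference over the 3 ways to part these arrays was 0.146 on the log2 scale, against a lower bound of 0.493 for the MCF7 fall. An array of the other line is argued against by the progesterone receptor gene PGR, chosen after its values were seen, which was at 501 or more in all T47D arrays and at 30 or less in the MCF7 arrays, and a probe at background by RHBDD2 intensities of 326 or more, against an array median of 25. For RHBDD2 RNA itself the T47D arrays argue against a fall like that of MCF7: 94.9% of control was left (95% interval 82.6% to 109%). In MCF7 the interval was 53.9% to 71.1%, both on the scale with the offset. Whether the siRNA entered or acted in the T47D cultures stays open. There 15.1% of probes had an unadjusted p under 0.05, above 5%, but differences between cultures that have nothing to do with RHBDD2 could give this too. A difference of the lines in how RHBDD2 responds to the siRNA also stays open, untested.

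The 10 lists whose response was lower in MCF7 than in T47D form the other pattern. Quantile normalization in particular is argued against as the whole cause. Under cyclic loess 9 of the 10 lists stayed past the threshold and all kept their direction. Cyclic loess works on the same values with the offset and also evens out differences that depend on intensity. It is therefore a limited test of normalization at large. Compression of dim probes by the offset stays open. On the deposited values with 1 decimal and no offset 9 of the 10 stayed past the threshold. Those values are also scaled by 1 factor per array, and genes blank on any array drop out of the list test. The comparison therefore does not isolate the offset. Brightness of the arrays stays open, since the mean log2 scale factor changed by -0.181 ± 0.20 (SE) in T47D and -0.147 ± 0.179 in MCF7, both within the spread of the arrays. A difference between the lines in how they respond stays open, untested, and so does a difference of cultures in many genes at once. With a correlation between genes estimated from the arrays the lowest camera adjusted p was 0.0507, in a test that also has only 4 degrees of freedom. With 2 arrays per group such differences and an effect of the siRNA cannot be told apart.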

How the results depend on the processing

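Deposited whole-number values, these values plus 16 and cyclic loess were chosen after seeing the data, the other alternatives before. For the 301 probes called in MCF7, the count was 142 under median scaling, 22 on the series table, 762 with a trend and robust moderation, 83 on the values plus 16 and 117 under cyclic loess, of which 83, 17, 259, 71 and 113 were shared with the 301. Whole-number values gave 317, of which 105 were shared with the 301, and only the arrays of that line 338, of which 186 were shared, so a like count did not mean the same probes. The values plus 16 gave 7 higher and 76 lower, and for the difference in response 55 and 7. RHBDD2 in MCF7 kept its direction and lost its call on the series table (-0.844, adjusted p = 0.068) and on the values plus 16 (-0.797, adjusted p = 0.0568). The T47D count of 0 became 55 with a trend and robust moderation and 186 on whole-number values, where rounding removes spread between duplicates, and the count of 0 for the mean of both lines became 4 under median scaling, 55 with a trend and robust moderation and 203 on whole-number values. The 261 differing responses became 23 under median scaling, 0 on the series table (3648 at an unadjusted p under 0.05), 686 with a trend and robust moderation, 431 on whole-number values, 62 on the values plus 16 and 126 under cyclic loess. The count between lines stayed within 1.5 times of 10782 in the alternatives run for it, which leave out the additive model, the block within line and the arrays of 1 line only.

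The 7 lists in MCF7 became 0 with an estimated correlation, 11 with the mean of probes, 22 under median scaling and 11 under cyclic loess. The 1 in T47D became 0 with an estimated correlation, the mean of probes or cyclic loess, 2 with fry, 2 (both lower) under median scaling and 5 on the series table. The 1 for the mean of both lines became 0 with an estimated correlation or on the series table, 2 with the mean of probes and 16 under median scaling. Apart from the stated construction of a setting, the cause was not tested.

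Leaving out each array in turn, the ranges were 0 to 607 probes in MCF7, 0 to 347 in T47D, 0 to 364 for the mean, 0 to 462 for the difference and 8707 to 11076 between lines, -0.786 to -0.605 for RHBDD2 in MCF7 and -0.183 to 0.0309 in T47D, and 5 to 8, 0 to 4 and 1 to 3 lists in MCF7, in T47D and for the mean. The group left with 1 array is assumed to vary like the others, and its comparison has less power. The labels' replicate numbers do not show pairs: the deviations of same-numbered arrays correlated at 0.0486 in MCF7 and 0.076 in T47D. With the replicate number as a block the MCF7 count was 67 and the difference 0 (3774 at an unadjusted p under 0.05), with RHBDD2 in MCF7 at -0.692 (adjusted p = 0.0639), and with a block within line the MCF7 count was 6 and RHBDD2 -0.692 (adjusted p = 0.069). The block moved the other counts by less than 1.5 times and changed no other call among them.

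For named genes other than RHBDD2, over all alternatives, 1745 results kept their side of the threshold, 603 lost and 43 gained it, and for called lists 254 kept and 50 lost it, with no reversed direction among these. The 1745 include genes without a call to lose and the genes named between the lines, which lost none. All 603 losses fell on genes called in MCF7 or for the difference in response. In MCF7, ARL2 kept its call in 7 of 20 alternatives and KCNH2 in 16. For the difference, KCNH2 kept it in 10 of 18, MTOR in 9 and SLC26A10P in 8. RHBDD2 in T47D, not past the threshold, turned from below to above 0 without T47D control array 1. Signal over background limits dim probes: the median raw intensity was 32 to 71, over a background of 7.08 to 13.8.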

Other observations

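The tests of lists between the lines, of sets of called probes in the other line and of gene families were chosen only after the results were seen, and the regrouping of arrays before. The gene lists were compared between the lines under control siRNA. Oxidative stress genes and NRF2 targets were lower in T47D than in MCF7 (camera adjusted p = 1.22e-05, and adjusted p = 0.16 with an estimated correlation), with 23 of 31 genes higher in MCF7 and 3 higher in T47D, and were lower also under median scaling (adjusted p = 0.00198). HMOX1 was at 168 ± 8.49 in MCF7 and 28.5 ± 0.707 in T47D, and ME1 at 517.5 ± 31.8 and 2 ± 0 (SD, n = 2 arrays). Genes of oxidative phosphorylation were higher in T47D (adjusted p = 0.00618, and adjusted p = 0.499 with an estimated correlation), with 28 of 50 genes higher in T47D and 8 in MCF7, and under median scaling as well (adjusted p = 4.74e-05). The proteasome (19 of 31 higher in MCF7, 5 in T47D, adjusted p = 0.00463, and adjusted p = 0.512 with an estimated correlation) and ribosome biogenesis with MYC targets (19 of 32 and 5, adjusted p = 0.0143, and adjusted p = 0.413 with an estimated correlation) were lower in T47D. Both of these calls ended under median scaling (adjusted p = 0.279 and 0.508). Under that scaling 5 other lists, not past the threshold after quantile normalization, were higher in T47D: mitosis and G2/M (adjusted p = 0.00646), cytosolic ribosomal proteins (0.0248), the TCA cycle (0.0263), endoplasmic reticulum chaperones (0.0422) and DNA replication (0.046). That scaling follows the offset of 50, which weighs less on the brighter T47D control arrays (median raw intensity 71 and 61, against 42 and 36 in MCF7). Lists higher in T47D under it, oxidative phosphorylation included, therefore cannot be told apart from array brightness. The same holds for both calls that ended under it.

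Of the 193 probes that fell in MCF7, 147 (76.2%) had a value above 0 in T47D arrays labelled RHBDD2 siRNA, with a median of 0.10. Of all probes tested, 47% had a value above 0 in T47D. Of the 108 that rose in MCF7, 45 had a value above 0 and 63 one below 0 in T47D, with a median of -0.01. Of the 193, 121 were also called for the difference in response, so the tally in part restates that result. Probes are not independent. The lines share no control arrays, but all arrays were normalized together.

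For the mean of both lines, the arrays were also parted into other groups of 4 and 4 with line as a covariate. In the real split limma called 0 probes (2608 at an unadjusted p under 0.05 in the additive model), and the highest other split called 4. With 0 calls in the real split, all 34 splits give at least as many by construction, so the comparison decides nothing.

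None of 11 gene families taken by symbol, among them zinc finger genes, solute carriers and keratins, was past the threshold after quantile normalization. This held in MCF7, in T47D and for the difference in response. The 339 olfactory receptor genes, which these lines would hardly use, had an adjusted p of 0.797 in MCF7 after quantile normalization and of 8.64e-08, upward, under median scaling. The DEAD-box helicases had an adjusted p of 0.0725 in MCF7, and downward of 0.014 under cyclic loess and 3.6e-05 under median scaling. Ubiquitin-conjugating enzymes (UBE2) had an adjusted p of 0.863, upward, and of 0.00539, downward, under median scaling. For the difference in response, median scaling put olfactory receptors (downward) and DEAD-box helicases (upward) past the threshold, each with camera adjusted p = 0.026. Under cyclic loess they had 0.249 and 0.213. Median scaling leaves differences that depend on array brightness, so the family calls under it cannot be told apart from those.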
